A study of Homo sapiens with 6 samples.

How the data were processed

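The series holds 6 RNA sequencing libraries from CT27 human trophoblast stem cells, titled ST cell in the labels: 3 controls, 1 labelled GATA2 knockdown and 2 labelled GATA3 knockdown. Per the labels, total RNA was used, libraries were made with a SMART-Seq low-input kit whose strandedness is not stated, and paired reads of 101 bp were sequenced on a NovaSeq instrument. The submitters' processing notes name GRCh38, bcl2fastq, STAR 2.6.1c, RSEM 1.3.1 and DESeq2 without stating roles, settings or the annotation release.

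The authors deposited, for each knockdown label, a table of raw counts per gene symbol with the same 3 control columns, and a DESeq2 result table. The counts were whole numbers; whether they are rounded RSEM estimates is not stated by the authors. In the deposited DESeq2 tables, per the file headers, the mean normalised signal, the log2 fold change with its standard error, the Wald score and the p-value with its adjusted form are given. The authors' mean signal was recomputed from the counts of the libraries in the matching table to within 1% for 100% of the genes they list. Each count table lists 58395 genes, of which 1543 carry a repeated symbol holding 0.052% to 0.087% of a library's counts; 0 count columns were left without a sample.

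Gene positions and types were taken from GENCODE 29 on GRCh38, where 98.9% of 56852 unique symbols were found, and are given 1-based. XIST and genes on the Y chromosome were left out of all named genes, tables and plots. CPM are counts scaled to a common library total, while fold changes use TMM scaling, so that ratios of CPM differ from the fold changes. With scaling by library size alone, the median log2 fold change of all genes moved from 0.017 to 0.20 under the GATA3 label and from 0.012 to 0.18 under the GATA2 label.

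Each comparison with the control used edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The libraries labelled GATA3 knockdown (n = 2) and the library labelled GATA2 knockdown (n = 1) were each compared with the 3 controls, and with each other in one fit of all 6 libraries. With 1 library, the spread came from the controls alone. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. The overlap of both comparisons was set against 20 simulated data sets of unchanged groups that share the controls.

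Before the data were examined, the comparisons, 20 gene lists (327 genes, 3 matched through an older symbol), the rule for named genes and most alternatives were fixed. The rule took GATA2 and GATA3, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and every knockdown library beyond every control, up to 4 called members per list by size of change, and, where a list had none, its most abundant member. The other members named were chosen after their values were seen, mostly because they passed adjusted over the list alone. Lists covered the GATA family, syncytiotrophoblast hormones, pregnancy-specific glycoproteins, fusion and its regulators, steroid synthesis, cholesterol synthesis, stem and cytotrophoblast, extravillous trophoblast, cell cycle, p53 targets, interferon response, hypoxia and glycolysis, the ATF4 and unfolded protein stress response, TGF-beta and BMP response, nutrient transporters, immediate early genes, and markers of stroma, endothelium, immune cells and amnion. They were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2, adjusted over the lists with at least 3 measured members), with an estimated correlation, and with fry. With the estimated correlation, the adjustment gave most lists under each label the same value, which therefore does not rank them.

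Alternatives were DESeq2 size factors, library size alone or upper quartile scaling; no filter, or a mean of at least 1 CPM; DESeq2 1.42.0, limma-voom, and a 2-fold minimum; leaving out each library; the replicate number as a block; and all 6 libraries in one fit. Added after the data were seen were the edgeR setting legacy=FALSE and DESeq2 without control 3.

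The fit of one library as a mixture of 2 others, chosen after the data were seen, was a weighted least squares fit on 10628 genes of at least 5 CPM, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. On simulated mixtures of 60% it returned 59.9% and 60.1%. Plots were drawn with matplotlib 3.10.9, and Wilson intervals (95%) came from scipy 1.17.1.

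The tests were tested on simulated negative binomial counts with the observed means, spread and library sizes. With 100 genes changed 2-fold and 100 changed 4-fold, the comparison under the GATA3 label recovered 7% and 76% with 5 unchanged genes called, that under the GATA2 label 0% and 0%, and the comparison between the labels 1% and 22%. A 2-fold shift of the cell cycle list was called by camera, while 0 of the 19 other lists were. Simulated genes varied independently of each other. In the data, the estimated correlation within lists ranged from -0.22 (GATA family) to 0.80 (cell cycle) under the GATA3 label. The simulation therefore does not show how often camera with its preset correlation gives false calls here.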

Results

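RNA was measured by sequencing in 6 libraries from CT27, a human trophoblast stem cell line derived from placenta. The labels' titles call the cells ST and do not expand the abbreviation, which in this field usually stands for syncytiotrophoblast, the fused hormone-producing layer of the placenta. There were 3 control libraries, 1 library labelled GATA2 knockdown and 2 libraries labelled GATA3 knockdown, and the labels do not state how the knockdowns or the controls were made. Total counts were 26216875, 24004663 and 25690748 in controls 1 to 3, 23745828 in the library labelled GATA2 knockdown, and 26434644 and 21867796 in replicates 1 and 2 labelled GATA3 knockdown. The genotype field of replicate 1 labelled GATA3 knockdown names GATA2, while its title and description name GATA3. Sample numbers in the labels were 4 to 6 for the controls, 51 for the library labelled GATA2 knockdown, and 56 and 57 for the libraries labelled GATA3 knockdown, so that any batch these numbers reflect and the group cannot be told apart.

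Trophoblast hormone transcripts made up a large part of all libraries. CGA, the alpha subunit of chorionic gonadotropin, took 6.50% ± 0.84 (SD, n = 3) of control counts, 5.31% ± 2.04 (SD, n = 2) in the libraries labelled GATA3 knockdown and 4.98% (95% Wilson interval 4.97% to 4.99%) in the library labelled GATA2 knockdown. The beta subunit genes CGB3, CGB5 and CGB8, whose close paralogs make the split of counts between them uncertain, together took 4.31% ± 0.43, 2.90% ± 0.97 and 2.86% (2.85% to 2.86%). Mitochondrially encoded transcripts took 5.13% ± 0.18 of control counts, 7.32% ± 0.86 under the GATA3 label and 8.61% (8.60% to 8.62%) under the GATA2 label. These intervals cover counting error only.

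The first question was whether each knockdown lowered its named target. GATA2 mRNA (chromosome 3, 128479427 to 128493185, GRCh38) was lower in all 3 knockdown libraries, whichever gene their label named. In CPM, counts scaled to a common library total, it measured 1097 ± 153 (SD, n = 3) in controls, 368 ± 6.07 (SD, n = 2) under the GATA3 label and 359 under the GATA2 label. GATA3 mRNA (chromosome 10, 8045378 to 8075203) was not lower under either label, at 564 ± 36.0 CPM in controls, 772 ± 98.3 under the GATA3 label and 813 under the GATA2 label.

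In the libraries labelled GATA3 knockdown, the log2 fold change of GATA2 against control was -1.76 (SE 0.24), with an edgeR adjusted p of 0.0559 over all genes tested and 0.00208 adjusted over the list alone, the list being the GATA family. That of GATA3 was 0.26 (SE 0.13, adjusted p = 0.292). In the library labelled GATA2 knockdown, the log2 fold change of GATA2 was -1.79 (SE 0.31), with an adjusted p of 0.249 over all genes and 0.0251 adjusted over the list alone, and that of GATA3 was 0.36 (SE 0.14, adjusted p = 0.348). The authors' deposited DESeq2 tables gave -1.78 (adjusted p = 1.256e-08) and -1.81 (0.000478) for GATA2 under the GATA3 and GATA2 labels, and 0.25 (0.332) and 0.35 (0.790) for GATA3. Without control 2, GATA2 passed the edgeR threshold under both labels, at log2 fold changes of -1.59 (adjusted p = 0.0251, GATA3 label; range over all alternatives 6.54e-09 to 0.738) and -1.63 (0.00433, GATA2 label; 0.000318 to 0.995). The controls left there were control 1 and control 3, itself close to a mixture that is 60.8% control 1. The spread between these controls may therefore be too small for that pass to count as separate support. GATA2 also passed with DESeq2 on all 3 controls (adjusted p = 6.54e-09 under the GATA3 label).

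**Figure D1:**
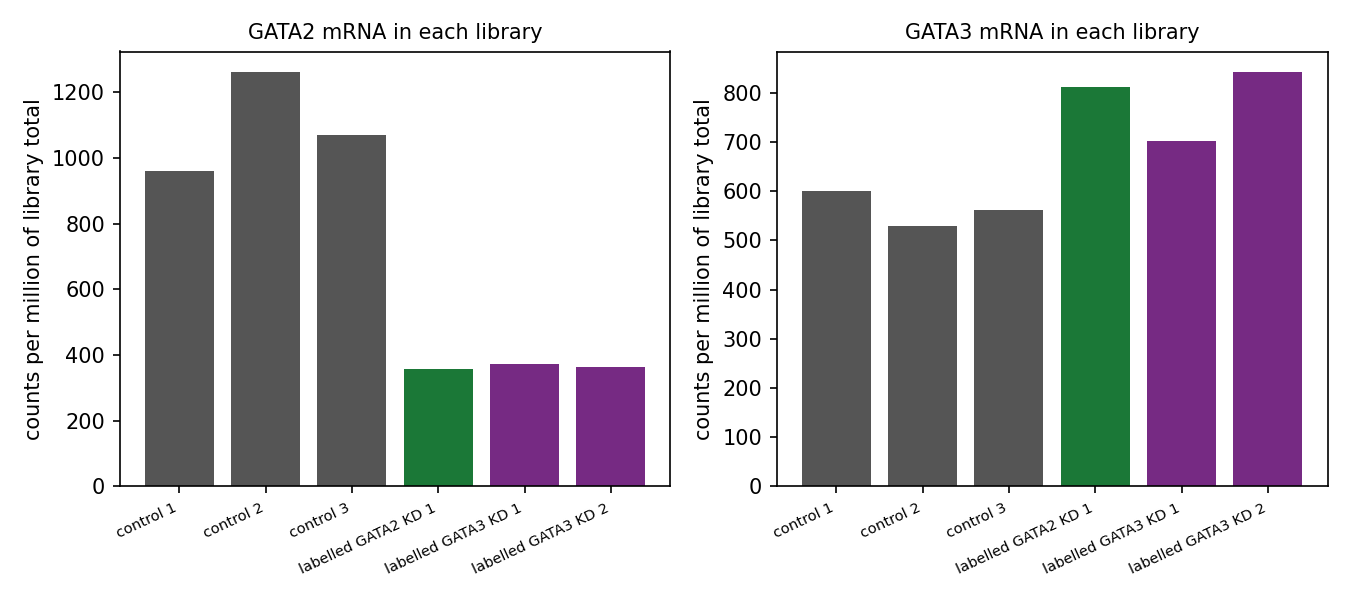
Counts per library total, scaled to CPM, (y axis, linear from 0) of GATA2 and GATA3 in each of the 6 libraries, with 1 bar per library, controls in grey, the GATA2 label in green and the GATA3 label in purple. GATA2 was at 359 to 373 in the 3 knockdown libraries and 960 to 1262 in the controls, whereas GATA3 was at 703 to 842 and 529 to 601.

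The second question was which transcripts differed between the libraries labelled GATA3 knockdown and the controls. Of 25 interferon response genes tested, 7 rose: OAS1 and OAS3, sensors of double-stranded RNA, were 27.0-fold and 20.9-fold higher, and BST2, MX2, HERC5, DDX60 and STAT2 also passed. The list passed camera (adjusted p = 8.24e-11) but not with an estimated correlation (adjusted p = 0.573 with an estimated correlation). The adjustment over the lists gave most of them this same value. The unadjusted p with an estimated correlation was 0.0377 for steroid synthesis, 0.133 for interferon response and 0.367 for cell cycle. How often this test would detect a shift was not assessed. PAPPA, a secreted placental protease that cleaves insulin-like growth factor binding proteins, fell, as did PSG2, a pregnancy-specific glycoprotein, and the cytotrophoblast genes TP63 and PAGE4. Of 17581 genes tested, 36 rose and 54 fell with edgeR. All 90 had both libraries beyond every control, as did 43.7% of all genes tested, where chance gives 20% over both directions for separate libraries. If control 3 were a pool of the other controls, chance for 2 against 2 would be 16.7% in each direction. Genes are also not independent of each other, so the excess over chance is no test of the group. With scaling by library size alone the balance turned, with 41 up and 28 down. Calls numbered 0 without control 1 or control 3, and 611 without control 2, which leaves control 1 and control 3, itself close to a mixture that is 60.8% control 1. They were also 0 without either library labelled GATA3 knockdown, but 1 library against 3 is a design in which 0% of simulated 4-fold changes were recovered.

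OAS1 (chromosome 12, 112906777 to 112933222) rose from 1.32 ± 0.55 to 42.6 ± 26.3 CPM, a log2 fold change of 4.76 (SE 0.50, adjusted p = 0.0450). Its neighbour OAS3 (chromosome 12, 112938352 to 112973249) rose from 9.06 ± 1.53 to 222 ± 133 CPM (log2 fold change 4.39, SE 0.33, adjusted p = 0.0406). PARP14 (3.41) and PARP12 (2.83), members of the poly-ADP-ribose polymerase family, and DDX60 (2.57), a helicase of the antiviral response, were also among the 8 largest rises at a mean of at least 5 CPM. The other 3 were SCRN1 (3.92), the collagen gene COL27A1 (2.82) and the homeobox gene DLX6 (2.73, chromosome 7, 97005548 to 97011039). Each of the 8 was higher in all 3 knockdown libraries than in all 3 controls. The rule for named genes required this of the libraries labelled GATA3 knockdown. The library labelled GATA2 knockdown lay close to a mixture of these, so it adds no separate support.

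ANXA1 (chromosome 9, 73151757 to 73170393), which encodes the phospholipid-binding protein annexin A1, fell from 1153 ± 158 to 132 ± 52.5 CPM (log2 fold change -3.35, SE 0.30, adjusted p = 0.0410). The secreted protease ADAMTS20 (chromosome 12, 43353866 to 43551921) fell from 524 ± 97.1 to 35.4 ± 13.7 CPM (log2 fold change -4.02, SE 0.39, adjusted p = 0.0448). GPC3 (-4.21), a heparan sulphate proteoglycan of the cell surface, KYNU (-3.67), an enzyme of tryptophan breakdown, and DSC3 (-3.99), a desmosomal cadherin, also fell. The remaining largest falls were the long non-coding RNA LINC02506 (-6.10), the adhesion receptor ADGRL3 (-4.93) and the kinase CAMK2D (-3.53).

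**Figure D2:**
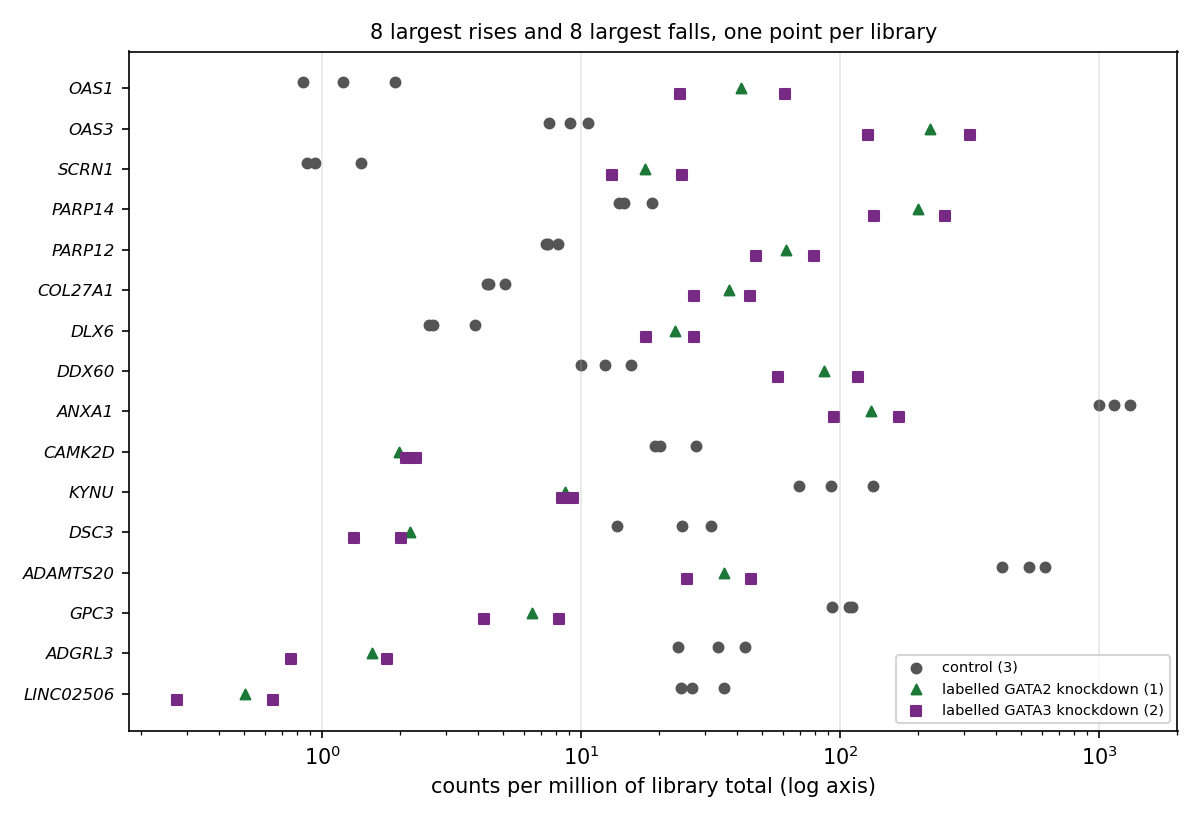
Counts per library total, scaled to CPM, (x axis, log scale) for the 8 largest rises and 8 largest falls called by edgeR between the libraries labelled GATA3 knockdown and the controls, with 1 point per library. All 3 controls (grey) were apart from all 3 knockdown libraries (green, GATA2 label; purple, GATA3 label) for every gene, as for ANXA1 at 1153 ± 158 in controls and 132 ± 52.5 under the GATA3 label. The rule for named genes required this of the libraries labelled GATA3 knockdown. The library labelled GATA2 knockdown lay close to a mixture of these.

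Among the interferon response genes, 19 rose adjusted over the list alone, with a median log2 fold change of 2.18 and 23 members higher. Within arms the list differed as well, by a median log2 ratio of -1.46 for control 1 over control 2 and of 0.71 for replicate 2 over replicate 1 labelled GATA3 knockdown. BST2 rose from 0.90 ± 0.23 to 9.24 ± 1.29 CPM and MX2 from 4.26 ± 0.37 to 21.8 ± 0.36. The camera test placed the list above other genes (adjusted p = 8.24e-11, and adjusted p = 0.573 with an estimated correlation). MX1 (-0.59) and RSAD2 (-0.15) were the 2 members with negative values, and neither passed. The mitochondrial share of counts was higher in the same libraries, as given above for each group.

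None of the listed cell cycle genes passed over all genes. Of 28 cell cycle genes, 27 were higher with a median log2 fold change of 0.77, 0 were called over all genes (3 by DESeq2, and 3 adjusted over the list alone), and camera placed the list higher (adjusted p = 7.89e-05; adjusted p = 0.573 with an estimated correlation). Without replicate 2 labelled GATA3 knockdown camera gave 0.0576. The 3 genes were E2F1 (1.06), AURKA (0.63) and MCM7 (0.51), while the most abundant member, MCM4, was at -0.02 and was positive with scaling by library size alone (0.19) or upper quartile (0.019). The same list differed by a median log2 ratio of 1.46 between controls 1 and 2, with all 27 members measured there higher in control 1, and by 0.84 between the replicates labelled GATA3 knockdown. Of 18 p53 target genes, 14 were higher with a median of 0.27, 0 were called (2 by DESeq2, 0 adjusted over the list alone) and camera gave an adjusted p of 0.0477 (adjusted p = 0.573 with an estimated correlation). This was 0.211 without control 2, 0.0603 without control 3, 0.425 without replicate 2 labelled GATA3 knockdown, and 0.0844 with scaling by library size alone. The p53 list differed by a median log2 ratio of 0.76 between controls 1 and 2 and of 0.48 between the replicates labelled GATA3 knockdown. CDKN1A, the most abundant of them, was at -0.03 and was positive with scaling by library size alone (0.17) or upper quartile (0.0096).

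Lists of syncytiotrophoblast function had negative medians, of a size also met between libraries of 1 arm for some of them. Of 24 hormone genes, 20 were lower with a median of -0.50; 1 fell over all genes, PAPPA, and 4 fell adjusted over the list alone (camera adjusted p = 0.00177; adjusted p = 0.573 with an estimated correlation). The hormone median was -0.36 for control 1 over control 2 and -0.51 for replicate 2 over replicate 1 labelled GATA3 knockdown, in which CGA took 3.87% and 6.75% of counts. PAPPA fell from 114 ± 23.4 to 25.2 ± 2.78 CPM (log2 fold change -2.38, SE 0.26, adjusted p = 0.0450), and PAPPA-AS1 (-2.41) lies wholly within it on the antisense strand, so that with strandedness not stated its counts are not separable from those of PAPPA. INHA, the inhibin alpha subunit (-1.64), and TFPI2 (-1.37) were 2 more of the 4, whereas LEP (0.95) and ADAM12 (0.85) had positive values and did not pass. Of 10 pregnancy-specific glycoprotein genes, which are close paralogs, 9 were lower with a median of -0.49; PSG2 fell from 458 ± 4.99 to 204 ± 21.8 CPM (log2 fold change -1.36), 2 fell adjusted over the list alone, and camera gave 0.00303 (adjusted p = 0.573 with an estimated correlation). Without replicate 2 labelled GATA3 knockdown, camera gave 0.310 for the hormone list and 0.162 for the glycoprotein list.

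Of 11 steroid synthesis genes, 10 were lower with a median of -0.47, and 0 were called over all genes (4 fell by DESeq2), while adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00303; adjusted p = 0.573 with an estimated correlation). CYP19A1, the placental aromatase, was at 3132 ± 459 CPM in controls and 1754 ± 9.67 under the GATA3 label (log2 fold change -1.01, SE 0.20, adjusted p = 0.0785; range over all alternatives 3.00e-06 to 0.830). CYP11A1 (-1.08) and HSD3B1 (-1.04), which carry out the first steps from cholesterol to progesterone, were among the 5. Of 21 cholesterol synthesis genes, 17 were lower with a median of -0.45, and 0 were called over all genes or adjusted over the list alone (2 fell by DESeq2; camera adjusted p = 0.0204; adjusted p = 0.573 with an estimated correlation). HMGCS1, the most abundant of these, was at -0.56 (SE 0.36). The cholesterol list had a median log2 ratio of 0.82 for control 1 over control 2. For cholesterol synthesis, camera gave 0.117 without control 1 and 0.425 without replicate 2 labelled GATA3 knockdown.

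Of 18 genes of cell fusion and its regulation, 14 were lower with a median of -0.45, and 0 were called over all genes (3 fell by DESeq2, 3 adjusted over the list alone; camera adjusted p = 0.0293; adjusted p = 0.573 with an estimated correlation). The 3 were ERVFRD-1, which encodes the fusion protein syncytin-2 (-1.34), its receptor MFSD2A (-1.34) and HOPX (-1.04). SDC1, the most abundant member, was at -1.13 (SE 0.49), and GCM1, a transcription factor that drives fusion, was at 0.26. Of 14 nutrient transporter genes, 12 were lower with a median of -0.28, and 0 were called (2 fell by DESeq2, 2 adjusted over the list alone; camera adjusted p = 0.0468; adjusted p = 0.573 with an estimated correlation). Those 2 were the folate receptor FOLR1 (-1.24) and the arginine transporter SLC7A1 (-0.76), and the most abundant member, SLC7A5, was at -0.72 (SE 0.41). The transporter median was -0.49 for control 1 over control 2 and -0.29 for replicate 2 over replicate 1 labelled GATA3 knockdown. Without replicate 2 labelled GATA3 knockdown, camera gave 0.282 for fusion and 0.649 for transport, and the latter was 0.203 without control 2.

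Markers of other trophoblast states were mixed. Of 19 stem and cytotrophoblast genes, 11 were lower with a median of -0.23; TP63 fell from 3.02 ± 0.60 to 0.19 ± 0.055 CPM and PAGE4 from 20.6 ± 3.58 to 7.59 ± 2.07, and 4 fell adjusted over the list alone (camera adjusted p = 0.0468; adjusted p = 0.573 with an estimated correlation). TP63 rests on few counts in the knockdown libraries, and the other members of the 4 were EGFR (-1.23) and PEG10 (-1.70). Camera gave 0.0849 for this list without control 1, 0.0619 without control 3 and 0.0955 without replicate 2 labelled GATA3 knockdown. Of 21 extravillous trophoblast genes, 10 were higher and 11 lower; 0 were called over all genes (1 rose and 7 fell by DESeq2), and adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.253; adjusted p = 0.573 with an estimated correlation). MCAM (1.34) was the member that rose, ITGA1 (-1.59) and TIMP3 (-1.04) were among those that fell, and FN1, the most abundant, was at -0.14 (SE 0.75) and was positive with scaling by library size alone (0.023) and with limma-voom (0.28). FN1 varied widely between controls, at 4392 ± 3250.3 CPM (SD, n = 3).

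The other lists did not pass camera. Of 16 hypoxia and glycolysis genes, 11 were higher (median 0.41), 0 were called over all genes (4 rose by DESeq2) and 4 rose adjusted over the list alone, namely EGLN3 (1.39), ANKRD37 (1.39), VEGFA (1.19) and LDHA (0.90), with camera at 0.0621 (adjusted p = 0.573 with an estimated correlation; 0.00242 without replicate 2 labelled GATA3 knockdown). SLC2A1, the most abundant, was at -0.15 and at 0.026 with scaling by library size alone. The hypoxia and glycolysis list had a median log2 ratio of -0.58 for replicate 2 over replicate 1 labelled GATA3 knockdown. Of its 15 members measured there, 2 were higher in replicate 2. For control 1 over control 2 the list median was -0.09. Of 5 GATA family genes and cofactors, 4 were higher (median 0.45) and, adjusted over the list alone, GATA2 fell and GATA4, at under 3 CPM, rose (camera 0.483). The stress response list of 19 (median -0.22; camera 0.151; most abundant member HSPA5, -0.62) had 0 called members (3 fell by DESeq2) and 1 fall adjusted over the list alone, SLC7A11 (-1.12), and camera gave 0.0404 without replicate 1 labelled GATA3 knockdown. The TGF-beta and BMP response list of 11 had a median of 0.22 and a mean of -0.09 (camera 0.536; adjusted p = 0.791 with an estimated correlation; CYR61, -0.71) and 0 called members (1 fell by DESeq2). The immediate early list of 11 had a median of -0.06 and a mean of 0.04 (camera 0.805; adjusted p = 0.898 with an estimated correlation; IER2, -0.47), with IER3 (1.58) up and FOSB down adjusted over the list alone.

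Markers of other placental cell types were few. Of 9 stroma genes tested, 6 were lower (median -0.30; camera 0.253, and 0.0210 without control 2), 0 were called over all genes (3 fell and 1 rose by DESeq2), and 3 fell and 1 rose adjusted over the list alone; COL1A2, a fibrillar collagen, was at 185 ± 124 CPM in controls and 4.14 ± 1.52 under the GATA3 label (-5.65, adjusted p = 0.0590), and TAGLN was at 0.30 (SE 0.69). Of 5 endothelial genes 3 were lower (median -0.72; camera 0.417; CDH5, -0.72), of 3 immune genes 2 were lower (median -0.65; camera 0.175; CSF1R, -0.65), and of 4 amnion genes 2 were higher (median -0.07, mean 0.03; camera 0.986; adjusted p = 0.991 with an estimated correlation; IGFBP3, 0.32). CDH5 and CSF1R are also expressed by trophoblast. Adjusted over the list alone, 1 endothelial and 1 immune gene fell, and 1 amnion gene rose and 1 fell. The GATA family, stress, stroma, endothelial and immune lists had an adjusted p = 0.573 with an estimated correlation.

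**Figure D3:**
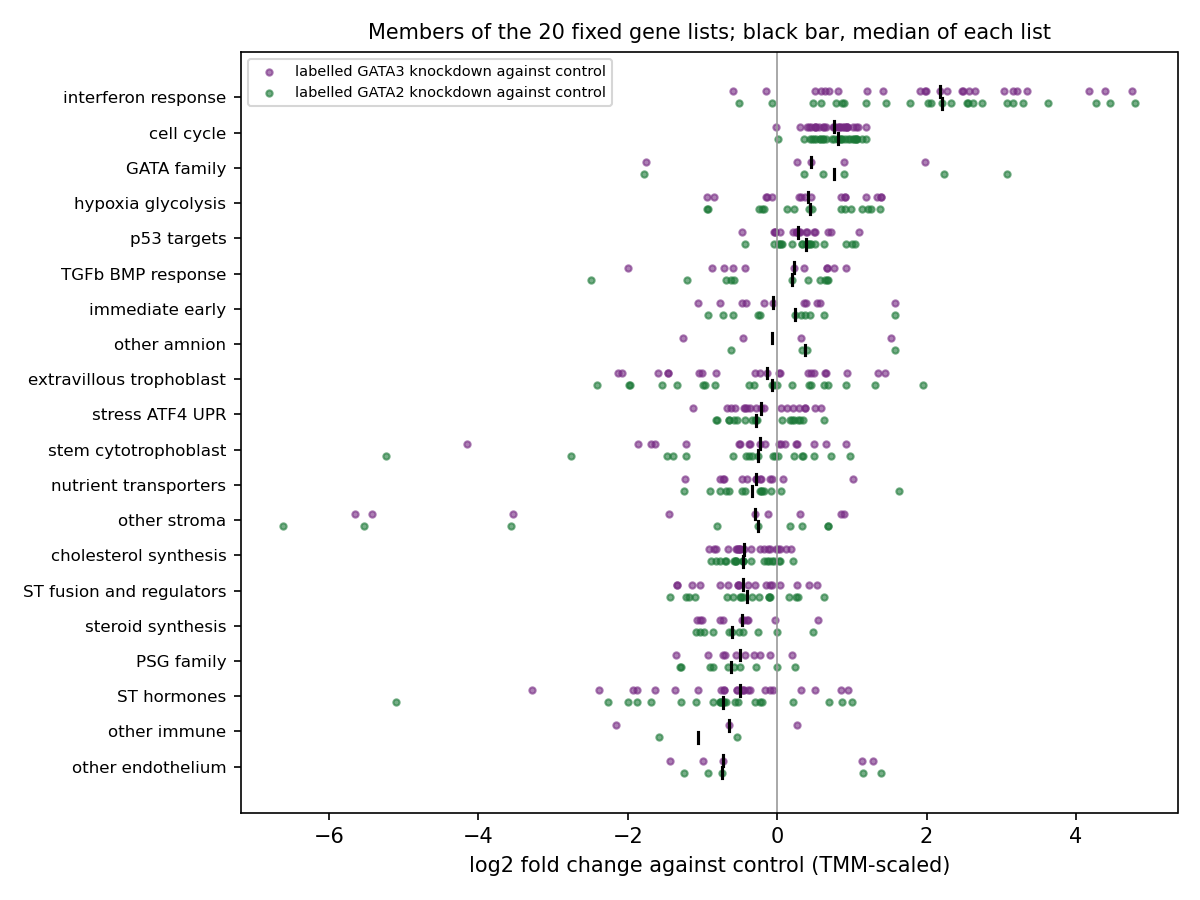
Log2 fold change against control (x axis, TMM-scaled) of each tested member of the 20 gene lists, with 1 point per gene, purple for the GATA3 label and green for the GATA2 label, and a black bar at each list's median. The interferon response list stood apart, with medians of 2.18 and 2.20.

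The 90 calls had adjusted p of 0.0406 to 0.0492, and 3923 genes had an unadjusted p under 0.05. The number of calls depended on the tool: DESeq2 called 1774 (728 up, 1046 down), limma-voom called 60, and the authors' table lists 1735, among them all 90 with the same sign. In the lists where edgeR called 0 members, limma-voom called 0 as well. With an estimated correlation, none of the 20 lists passed. Of the 20 lists, 10 passed camera, and without replicate 2 labelled GATA3 knockdown 3 did: interferon response (1.93e-07), steroid synthesis (0.0348), and hypoxia and glycolysis (0.00242).

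The third question was which transcripts differed in the library labelled GATA2 knockdown. The values followed those under the GATA3 label: PARP14 (3.50) and OAS3, at 223 CPM against 9.06 ± 1.53 in controls, were higher, and EGFR, the receptor of epidermal growth factor, was at 897 CPM against 1863 ± 41.9 (log2 fold change -1.22, SE 0.18, adjusted p = 0.249). Of 18221 genes tested, edgeR called 0, with 2664 at an unadjusted p under 0.05. For the same comparison limma-voom called 0, DESeq2 called 389 (155 up, 234 down) and the authors' table lists 379 (160 up, 219 down). The fit assumed that the single library varied like the controls. Without control 2 edgeR called 1501, including GATA2, EGFR, CYP19A1, HMGCS1, CYR61 and CSF1R of the genes named here; the controls left were then control 1 and control 3, whose counts lay close to a mixture that is 60.8% control 1.

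Of 25 interferon response genes, 23 were higher under the GATA2 label (median 2.20), 10 rose adjusted over the list alone and 11 by DESeq2, and camera gave an adjusted p of 6.23e-10. Its most abundant member was IFI6, at 999 CPM against 637 ± 18.5 (0.48, SE 0.17). All 28 cell cycle genes had positive values (median 0.81; camera 0.000251), although MCM4 (0.02) was at -0.0031 with DESeq2 size factors. The p53 targets (median 0.39, 17 of 19 higher; camera 0.0464) and the hypoxia and glycolysis genes (median 0.45, 11 of 16 higher, 5 adjusted over the list alone; camera 0.0200) passed camera as well; CDKN1A was at 0.02 and SLC2A1 at -0.24. For the p53 targets camera gave 0.135 without control 2, 0.0649 without control 3 and 0.0656 with scaling by library size alone, and for hypoxia and glycolysis 0.112 without control 1. All of these lists had an adjusted p = 0.650 with an estimated correlation.

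Values of the syncytiotrophoblast lists in the library labelled GATA2 knockdown rest on 1 library and the same 3 controls, in a fit that recovered 0% of simulated 4-fold changes. Of 24 hormone genes 20 were lower (median -0.73; camera 0.000594), with CGA at -0.56 (SE 0.43). Of 10 pregnancy-specific glycoprotein genes 9 were lower (median -0.62; 3 adjusted over the list alone; camera 0.00113), with PSG3 at -0.57 (SE 0.19). Of 11 steroid synthesis genes 10 were lower (median -0.60; 4 adjusted over the list alone; camera 0.00380), with CYP19A1 at -0.98 (SE 0.22), and of 21 cholesterol synthesis genes 18 were lower (median -0.45; camera 0.0191), with HMGCS1 at -0.58. These 4 lists had an adjusted p = 0.650 with an estimated correlation, and cholesterol synthesis was at 0.112 without control 1.

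Of the lists not past camera under the GATA2 label, the fusion list had a median of -0.40 (camera 0.0640; SDC1, -1.23), the stem and cytotrophoblast list -0.26 (0.0543, with 3 falls adjusted over the list alone), the nutrient transporters -0.33 (0.102; SLC7A5, -0.77) and the extravillous trophoblast list -0.07 (0.378; FN1, -0.07, which was 0.059 with scaling by library size alone). The GATA family list had a median of 0.76 (0.240, with GATA2 down adjusted over the list alone), the stress list -0.28 (0.188; HSPA5, -0.64) and the immediate early list 0.24 (0.638; IER2, -0.59, with 1 rise adjusted over the list alone). The TGF-beta and BMP list had a median of 0.20 and a mean of -0.22 (0.673; CYR61, -0.69), the stroma list a median of -0.26 (0.378; TAGLN, 0.33), the endothelial list -0.73 (0.692; CDH5, -0.73) and the amnion list 0.37 (0.622; IGFBP3, 0.40). Only 2 immune genes were measured (median -1.06; CSF1R, -0.54; 1 fell adjusted over the list alone), too few for a test. Without control 2 the fusion (0.0315), stem (0.0302) and stroma (0.0216) lists passed camera, and without control 1 the nutrient transporters did (0.0285). With an estimated correlation the adjusted p was 0.650 for the GATA family, fusion, stem, transporter, extravillous and stress lists, 0.749 for stroma, 0.786 for the immediate early, endothelial and amnion lists, and 0.831 for TGF-beta and BMP.

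The fourth question was whether the labels GATA2 and GATA3 marked different responses. GATA2 (0.03, SE 0.30) and GATA3 (-0.10, SE 0.17) had an adjusted p of 1 for the difference between the libraries labelled GATA3 knockdown and the one labelled GATA2 knockdown. Of 18862 genes, edgeR called 0 between them (141 at an unadjusted p under 0.05), and so did DESeq2 and limma-voom. The library labelled GATA2 knockdown lay outside the range of the 2 labelled GATA3 knockdown in 37.7% of genes, where chance gives 66.7% for separate libraries. Its counts lay close to a mixture of theirs, so this low share does not show that the labels marked the same response. The edgeR test between the labels recovered 22% of simulated 4-fold differences, so that a difference of this size would often not have been detectable.

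Across 17482 genes the fold changes under the GATA2 and GATA3 labels had a Pearson correlation of 0.907, against a mean of 0.301 in 20 simulations of unchanged groups sharing the same controls, and 87.6% had the same sign against 60.3%. The covariance was 0.653, and 0.0749 in the simulations. The simulations treat the library labelled GATA2 knockdown as independent of those labelled GATA3 knockdown, yet its counts lay close to a mixture of them (49.1% and 50.9%). Genes are not independent replicates, and 3 controls could not be divided so that each comparison had at least 2 of its own. With edgeR 0 genes were called under both labels, whereas DESeq2 called 380 in both (153 up, 227 down and 0 in opposite directions), a count for which no value under shared controls was computed.

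Libraries within each arm were related in a way the labels do not describe. Control 3 lay close to a mixture of 60.8% control 1 and 39.2% control 2: of 1671 genes at least 2-fold apart between controls 1 and 2, 1669 (99.9%) lay between them in control 3. FN1, at 7394 CPM in control 1 and 940 in control 2, was 4842 in control 3, where the mixture gave 4861. The library labelled GATA2 knockdown lay close to a mixture of 49.1% and 50.9% of replicates 1 and 2 labelled GATA3 knockdown, with 509 of 510 such genes (99.8%) between them. Of all 10628 genes compared, 79.9% and 72.5% lay between, and chi-squared per degree of freedom was 2.03 and 8.76. Between the opposite arm's libraries, over genes at least 2-fold apart there, 55.7% lay between for control 3 and 48.8% for the library labelled GATA2 knockdown. Libraries of opposite arms also differ by group, so these shares do not test whether either library was a pool. Without control 3, edgeR called 0 genes under the GATA3 label, while DESeq2 called 424, among them all 90.

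**Figure D4:**
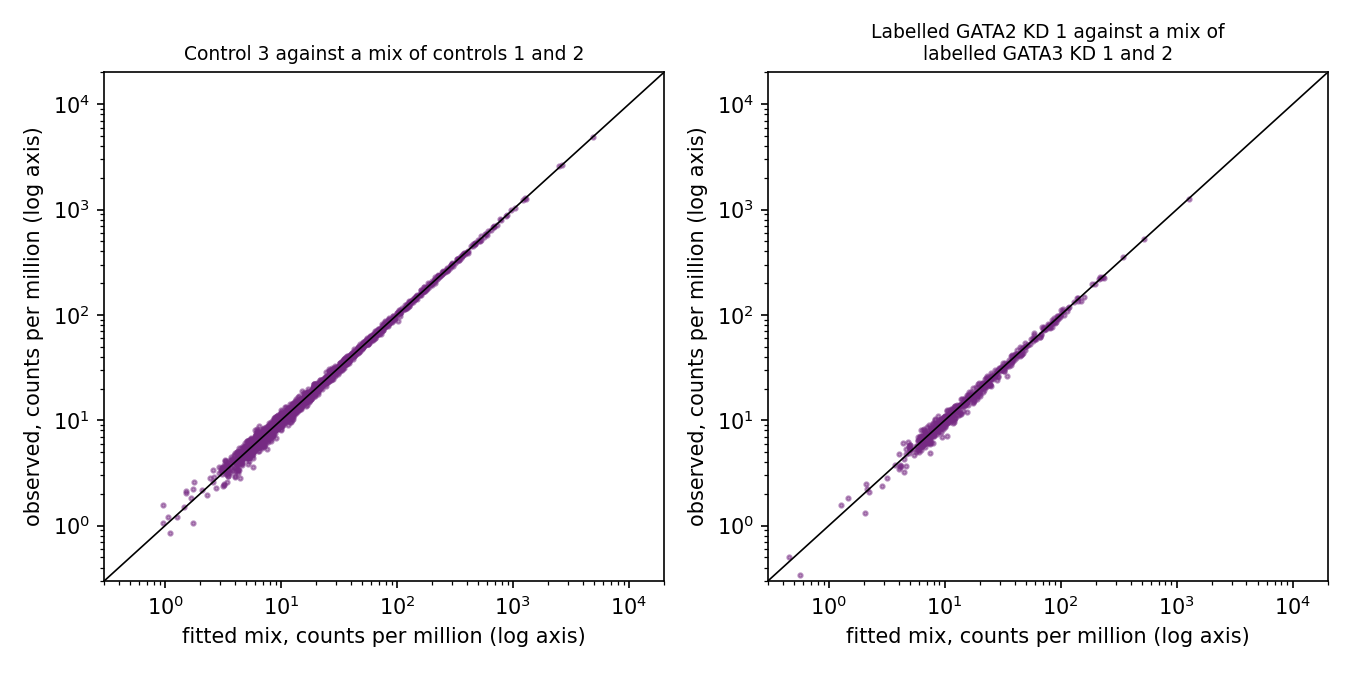
Observed against fitted CPM (both axes log scale) for genes at least 2-fold apart between the outer libraries, with 1 point per gene; the line marks equality. Control 3 followed the fit to controls 1 and 2 over 1671 genes, and the library labelled GATA2 knockdown followed the fit to both libraries labelled GATA3 knockdown over 510.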

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

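The tests with edgeR legacy=FALSE and with DESeq2 without control 3 were chosen after the results were seen. For the comparison under the GATA3 label, 503 values for its named genes kept direction and side of the threshold, 115 kept direction but no longer passed, 9 passed newly and 19 reversed; under the GATA2 label these were 270, 0, 9 and 15, and between the labels 27, 0, 0 and 1. The 90 genes called under the GATA3 label became 450 with no filter on low counts, 1774 with DESeq2, 175 with legacy=FALSE and 424 with DESeq2 without control 3, and ranged from 0 to 611 when 1 library was left out. With the replicate number as a block there were 0 calls; changes of genes did not pair by number (r = -0.54 between control 1 and replicate 1 labelled GATA3 knockdown, each against its group). For the comparison under the GATA2 label alone, no paired analysis was possible because its single library would leave no residual degrees of freedom beside the replicate block. The 0 genes under the GATA2 label became 7 with no filter, 389 with DESeq2 and 71 with DESeq2 without control 3, and ranged from 0 to 1501. Calls under both labels became 380 with DESeq2 and 67 without control 3. Of 10 lists past camera under the GATA3 label and 8 under the GATA2 label, 0 and 0 passed with an estimated correlation and 0 and 0 with fry, while 9 and 8 of all lists passed fry in either direction, among them interferon response, hormones, glycoproteins and steroid synthesis under both labels. The lists past camera under the GATA3 label ranged from 3 to 11 when 1 library was left out. The cause was not tested.

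All reversed genes were uncalled. Under the GATA3 label, library size alone gave FN1 0.023, MCM4 0.19, CDKN1A 0.17 and SLC2A1 0.026; upper quartile gave MCM4 0.019 and CDKN1A 0.0096; limma-voom gave FN1 0.28; and the replicate block gave FN1 0.54 and CYR61 0.24. Leaving out 1 library gave -0.61 to 0.42 for FN1, -0.31 to 0.21 for MCM4, -0.091 to 0.026 for CDKN1A, -0.73 to 0.25 for SLC2A1, -0.15 to 0.82 for TAGLN and -0.16 to 0.91 for IGFBP3. Under the GATA2 label, MCM4 was -0.0031 with DESeq2 size factors in edgeR and -0.0031 with DESeq2, FN1 was 0.059 with library size alone and 0.35 with limma-voom, and DESeq2 without control 3 gave FN1 0.010, MCM4 -0.031 and CDKN1A -0.011. Leaving out 1 control gave -0.54 to 0.49 for FN1, -0.026 to 0.068 for MCM4, -0.031 to 0.072 for CDKN1A, -0.50 to 0.13 for SLC2A1, -0.13 to 0.84 for TAGLN and -0.079 to 0.98 for IGFBP3. Between the labels, GATA2 ranged from -0.12 to 0.17. The cause was not tested. At these depths, 3 counts correspond to 0.113 to 0.137 CPM, so changes of genes near that level were not detectable.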

Other observations

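Apart from the edgeR tests of single genes, the list medians and fry, the tests in this part and most genes named in it were chosen after the results were seen. Cancer-testis genes of the X chromosome are normally silent outside the germline and placenta, and were not a fixed list. Of 13 genes of the MAGEA, MAGEC, CSAG, PAGE and XAGE families with a mean above 1 CPM over the 6 libraries, 9 were above every control in all 3 knockdown libraries. PAGE4, a member of the stem and cytotrophoblast list, was the 1 gene below. Among the 9, CSAG1, CSAG3, MAGEA11 and MAGEA12 averaged under 1 CPM in controls and reached that mean only through the knockdown libraries, which favours rises in this count. The GAGE and MAGEB families were also searched, and no member was counted. Among all 14503 genes above 1 CPM, 30.3% were above every control and 11.9% below in CPM, a scale on which the median log2 fold change was 0.20 rather than 0.017, and enrichment of these families was not tested. MAGEA3 was at 2.86, 0 and 2.22 CPM in controls 1 to 3, at 46.3 and 61.0 in the libraries labelled GATA3 knockdown and at 52.5 under the GATA2 label. MAGEA4, MAGEA6, MAGEA10, MAGEA12 and CSAG1 were above every control as well, yet only XAGE3 (1.29, adjusted p = 0.0443) and PAGE4 passed edgeR, and members of these families are close paralogs whose counts are uncertain. The adjacent homeobox genes DLX5 (7.70 ± 0.39 to 36.0 ± 8.65 CPM, log2 fold change 2.07) and DLX6 rose together under the GATA3 label, as did the cell cycle regulator E2F8 (1.79), the receptor NRP1 (1.29) and the nuclear body gene SP100 (1.88).

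The replicates differed within each arm. Over genes above 0 in every library, 1667 of 10624 genes were at least 2-fold apart between controls 1 and 2, and between the libraries labelled GATA3 knockdown 508 were, and the overlap of these genes was not tested. Across genes, which are not independent replicates, the difference of control 1 from control 2 had a correlation of 0.55 with that of replicate 2 from replicate 1 labelled GATA3 knockdown. All 27 cell cycle genes measured were higher in control 1 (median log2 ratio 1.46) and in replicate 2 (0.84), stem and cytotrophoblast genes had medians of 0.74 and 0.41, and hormone genes had -0.36 and -0.51. Interferon response genes went the other way between the controls (-1.46) and were higher in replicate 2 (0.71). Cholesterol synthesis genes had medians of 0.82 between the controls (20 of 21 higher in control 1) and -0.17 between the libraries labelled GATA3 knockdown (8 of 21 higher in replicate 2).

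GATA2 was lower and GATA3 was not in the libraries labelled GATA3 knockdown. An exchange of the labels between the groups would make the library labelled GATA2 knockdown a GATA3 knockdown. Its GATA3 mRNA was 1.54 times the lowest control rather than below it. This argues against an exchange only if a GATA3 knockdown lowers GATA3 mRNA, which these data cannot show. That library also lay close to a mixture of those labelled GATA3 knockdown, so its GATA3 value may only repeat theirs. If that library was a pool, its value says nothing of a separate culture. A wrong knockdown label on the libraries labelled GATA3 stays open, as the genotype field of one names GATA2, but was not tested by their lower GATA3 value, 1.17 times the highest control, which is the pattern itself. A loss of GATA3 protein without a fall of its mRNA, with GATA2 falling after it, stays open, because the test between the labels recovered only 22% of simulated 4-fold differences. Protein was not measured in these data.

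Control 3 and the library labelled GATA2 knockdown each lay between a pair of other libraries. A merge after sequencing of the same reads that were counted in the outer libraries is argued against. The median squared deviation from the mixture, in units of counting variance, was 1.10 and 1.83, against 0.214 and 0.222 for reads drawn from the outer libraries' own counts. A merge of other reads of the outer libraries was not simulated. For pooled RNA or cDNA of the outer libraries, 99.9% and 99.8% of genes at least 2-fold apart lay between, but of all 10628 genes 79.9% and 72.5% did, chi-squared per degree of freedom was 2.03 and 8.76, MALAT1 was at 971 CPM where the second mixture gave 645, and the mitochondrial shares (4.94% and 8.61%) lay outside those of the outer libraries (5.13% and 5.30%; 7.93% and 6.71%). Pooling, with library preparation moving these values, and separate cultures that hold different shares of the same cell states, the biological explanation, both stay open and cannot be told apart, as the correlation of 0.55 across genes leaves the latter possible. If both were pools, control 3 and the library labelled GATA2 knockdown would be no separate samples. The likeness of the labels and the GATA3 level under the GATA2 label would then follow from the libraries labelled GATA3 knockdown. Without control 3, edgeR called 0 genes under the GATA3 label and DESeq2, a setting added after the data were seen, called 424.

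Interferon response genes were higher in the 3 knockdown libraries. Of 23 members above 1 CPM, 20 (87.0%) were above every control in all 3, against 30.3% of all 14503 genes on the same scale. Spread between cultures stays open even so. Most members moved together within arms (-1.46 and 0.71, above), and fry gave an adjusted p of 0.0978 under the GATA3 label. Between the controls, the called members OAS3, DDX60 and MX2 went against that median, being higher in control 1. The called members OAS1, BST2, HERC5 and STAT2 were higher in control 2. A list moving as 1 would lie above by chance in 5% of cases for 6 separate libraries. For 2 against 2, if the intermediate libraries were pools, this is 16.7%. A possible batch of the knockdown libraries (median 2.20 under the GATA2 label) and a possible response to a knockdown construct (median 2.18 under the GATA3 label) cannot be told apart: the labels state neither a batch nor how the knockdowns and controls were made, and either would run with the group. Loss of GATA2 itself also stays open and was not tested. A library with a control construct, made alongside the knockdown libraries, could separate loss of GATA2 from a batch or a construct response. It would not tell a batch and a construct response apart.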
